A study of Mus musculus with 10 samples.

How the data were processed

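The samples were RNA of mouse embryos of B6D2F1 parentage, 8-cell embryos at E2.25, ICM and TE at E3.5, and Epiblast and ExE at E6.5, 2 libraries per group. Per the labels, zygotes were grown in KSOM, 8-cell embryos were held with aphidicolin and stripped of zona and polar bodies, ICM and TE were separated by laser from matched blastocysts, and E6.5 conceptuses were bisected. RNA was amplified with a SMART-seq v4 kit, a full-length method without molecular identifiers, and libraries were made with Nextera XT. The submitters' processing notes name TopHat, kallisto and mm10, with no versions and no roles. The deposited files hold kallisto's columns for 34997 RefSeq transcripts per library: expected counts (est_counts), which the authors left unnormalised, TPM, which the authors' kallisto run scaled per library after division by effective length, and transcript length and effective length in bases, as other columns of the deposited files. kallisto assigns reads to spliced transcripts alone, so intronic and intergenic reads are not in the files.

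Transcripts were matched to genes by RefSeq accession, 34661 through a RefSeq gene table of GRCm38 and 192 through GENCODE, and 144 had no match and held 0.89 to 2.37% of the counts of a library. Expected counts were summed over 24453 genes and rounded. Library totals were 32657612 to 58491942 counts, of which 32124330 to 57620519 were matched to genes, and 3 counts of the matched ones stand at 0.0521 to 0.0934 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had 0 counts, the fold is given as at least the ratio to 3 counts over the group.

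Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM, quasi-likelihood F-test, all 10 libraries in 1 fit of 5 groups with 5 residual degrees of freedom), with Benjamini-Hochberg adjustment at 0.05 over the 20264 genes tested in each contrast, and 4189 genes were not tested. The contrasts were ExE minus Epiblast, TE minus ICM, the difference of these 2, Epiblast minus ICM, ExE minus TE, ICM minus 8-cell and TE minus 8-cell. All tests are two-sided. The test was tried on simulated ExE and Epiblast counts, in which it recovered 12% of 100 genes changed by a log2 fold of 1 and 30% of 100 changed by 2, with 3 false calls, and made 0 calls where nothing changed. DESeq2 1.42.0 recovered 25% and 44% with 45 false calls, and made 34 calls where nothing changed. For limma 3.58.1 it was 12% and 26% with 4 false calls, and 0 calls where nothing changed. All other genes of the 20264 were left unchanged in the simulation, so these shares do not measure recovery in the data.

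The 26 gene lists, the tests and the rule for naming genes were fixed before the data were examined. They are the DNA methylation machinery, Polycomb complexes, naive pluripotency, primed epiblast, ExE and trophoblast stem cell, trophectoderm, primitive and visceral endoderm, ectoplacental cone and giant cell, decidua and blood, primitive streak and mesoderm, FGF, WNT, and NODAL and BMP signalling, germline genes, oocyte and two-cell genes, imprinted genes, developmental transcription factors, clustered protocadherins, p53 targets, dissociation stress, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, cell cycle, and Y-linked genes with Xist. Lists overlap in some genes. Each list was tested with camera (preset inter-gene correlation 0.01), adjusted over 182 tests, which compares its genes with all others, and again with an estimated correlation. Counts of members are over all genes tested and, adjusted over the list alone, within the list. Named genes were the 8 with the largest rise and the 8 with the largest fall per contrast (6 for the difference) among changed genes with at least 20 CPM in the higher group and no overlap between replicates, the members of a list with the smallest adjusted p, up to 4, and 10 reference genes. The texts print a part of them.

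Alternatives fixed before the data were examined were DESeq2 size factors, library totals in place of TMM, DESeq2, no filter on low counts, at least 1 CPM in 2 libraries, the groups of a contrast alone, a transcript length offset, limma on log2(TPM + 1), on log2(TPM + 0.1) and with a TPM minimum of 1, a fold threshold, the replicate number as a block (a replicate block over all groups or within a stage), and each library left out in turn. 3 were added after the data were seen: leaving out ExE replicate 1 with Epiblast replicate 1, keeping genes of at least 5 CPM alone, and TMM factors from genes of at least 20 CPM alone. Leaving out a library leaves its group with 1, whose spread is then taken to be that of the other groups. Background was measured on 1459 olfactory and vomeronasal receptor genes, as counts per kilobase scaled by library total without TMM. Figures and permutation tests used Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.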

Results

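RNA of mouse embryos was sequenced at the 8-cell stage (E2.25), in the inner cell mass (ICM) and trophectoderm (TE) of E3.5 blastocysts, and in the epiblast and extraembryonic ectoderm (ExE) of E6.5 conceptuses, with 2 libraries per group and 10 in all. ICM gives rise to the epiblast and the primitive endoderm, TE to the trophoblast, and ExE is the part of the trophoblast that lies on the epiblast. The epiblast samples are labelled as its proximal part. The series frames the data as a comparison of expression in ExE and in cancer, and its 10 libraries are all of embryos. Total estimated counts were 54864532 and 49425195 in the 8-cell libraries, 42335591 and 47463458 in ICM, and 58491942 and 45700014 in TE. They were 41627049 and 32657612 in Epiblast, and 45089224 and 47696645 in ExE. Values are CPM, counts scaled by library size and TMM factor, as mean ± SD over 2 libraries (n = 2 in each group), and coordinates are those of GRCm38, the assembly also called mm10. The p-values measure the spread between these samples, since the labels do not say whether the 2 libraries of a group came from separate pools of embryos. Nor do they say which ICM and TE, or Epiblast and ExE, libraries share embryos, so the main fit used no pairing. The replicate block follows replicate numbers and is no test of pairing. Across genes, log2 differences between replicates 2 and 1 had r = −0.038 between ICM and TE, and −0.395 between Epiblast and ExE.

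Component 1 of the expression values held 37.6% of the variance and component 2 held 23.3%. ExE replicate 1 lay at 116.18 on component 1 and ExE replicate 2 at 53.57, while Epiblast lay at 184.52 and 194.91. The number of genes with at least 10 counts ran from 14633 in ExE replicate 2 to 18915 in Epiblast replicate 2. Counts on olfactory and vomeronasal receptor genes, which serve sensory neurons, ran from 0.0551 CPM per kilobase in TE replicate 1 to 0.894 in Epiblast replicate 2, and were 0.504 and 0.0611 in the ExE libraries.

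**Figure D1:**
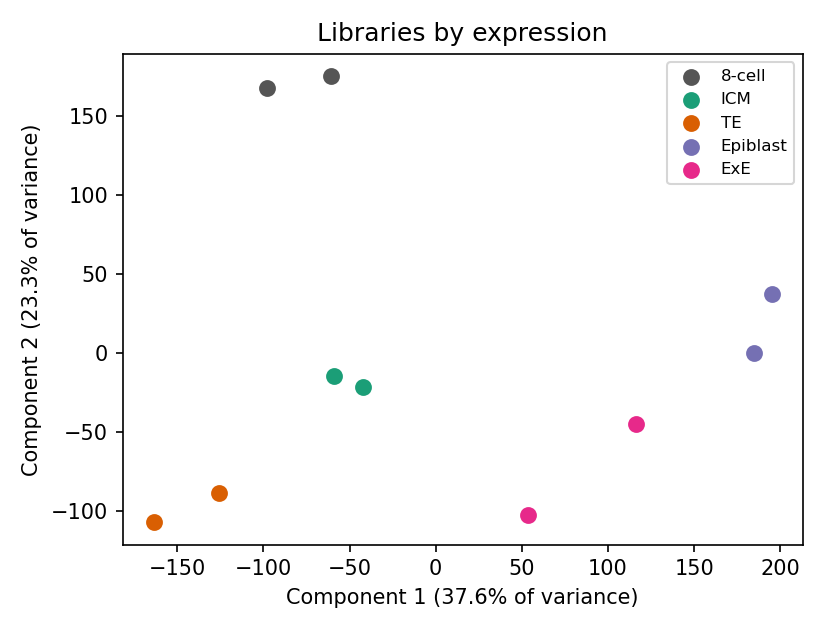
Principal components of the 10 libraries on log2 CPM, 1 point per library, coloured by group. The share of variance of each axis is printed on it (37.6% and 23.3%), and the ExE libraries lie farther apart than those of Epiblast.

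ExE and Epiblast were compared to ask how trophoblast and embryo proper differ at E6.5. ExE held the trophoblast regulators Elf5 (270 ± 42.9 against 0.177 ± 0.1 CPM, log2 fold change 10.59, adjusted p = 2.32e-05), Cdx2 (70.9 ± 23.8 against 0.286 ± 0.195 CPM, log2 fold change 7.90, adjusted p = 1.41e-06) and Tfap2c (303 ± 2.27 against 1.19 ± 0.0318 CPM, log2 fold change 7.99, adjusted p = 5.45e-09). The ligand Wnt7b stood at 496 ± 95 against 0.293 ± 0.0647 CPM, and the ligand Wnt6 at 92.9 ± 29.1 against 0.023 ± 0.00251 CPM, the latter from 2 counts in Epiblast. Epiblast held the pluripotency factor Pou5f1 (483 ± 12.6 against 13.2 ± 15.3 CPM, log2 fold change −5.19) and the anterior regulator Otx2 (214 ± 37 against 3.66 ± 4.33 CPM, log2 fold change −5.86). Nanog, a pluripotency factor, was lower in ExE with a log2 fold change of −2.89 (adjusted p = 0.0006). Pou5f1 stood at 24.1 CPM in ExE replicate 1 and 2.38 in ExE replicate 2.

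The DNA methyltransferases moved apart between the E6.5 tissues. The de novo enzymes were lower in ExE, Dnmt3a (chromosome 12, 3801559 to 3914443) at 32.1 ± 8.9 against 563 ± 64.4 CPM (log2 fold change −4.13, adjusted p = 7.4e-07) and Dnmt3b (chromosome 2, 153649411 to 153687730) at 1394 ± 171 against 3854 ± 214 CPM (log2 fold change −1.47, adjusted p = 9.04e-05). Their cofactor Dnmt3l (chromosome 10, 78042287 to 78063622) was higher in ExE, at 120 ± 3.8 against 11.5 ± 0.97 CPM (log2 fold change 3.39, adjusted p = 1.65e-06). The maintenance enzyme Dnmt1 (chromosome 9, 20907206 to 20959888) rose by a log2 fold change of 0.88 (adjusted p = 0.00556), a call that was lost without Epiblast replicate 2 (0.83, adjusted p = 0.0507) and without ExE replicate 2 (0.73, adjusted p = 0.0605). Of 17 measured genes of the DNA methylation machinery, 4 rose and 3 fell in ExE, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.781), a majority of rises that turned to 3 and 4 when libraries were scaled by their totals.

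**Figure D2:**
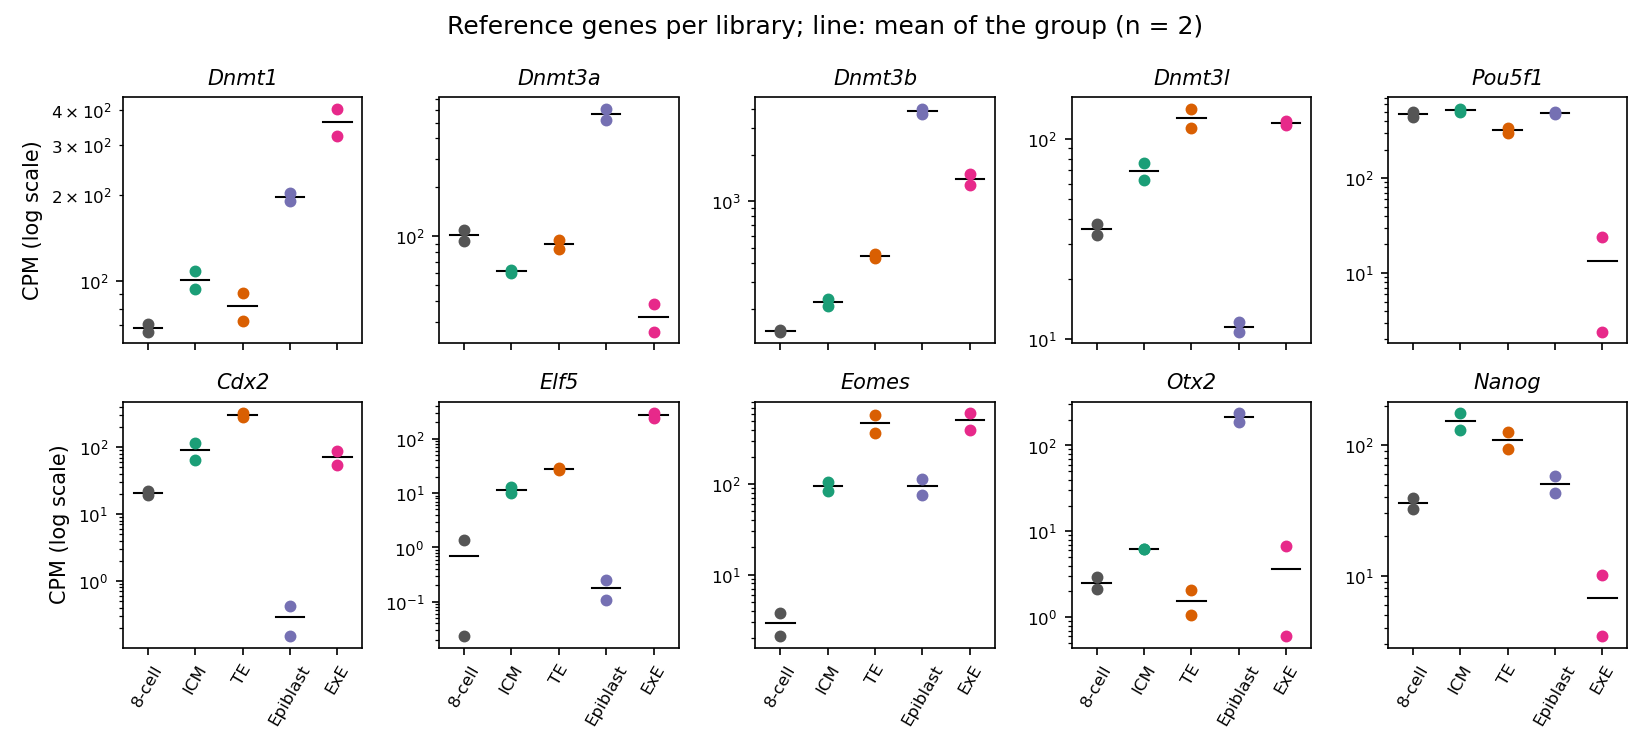
CPM of 10 reference genes, 1 panel per gene, on a log axis. Points are libraries, lines are means of 2 libraries, and groups are ordered by stage; Dnmt3a and Dnmt3b peak in Epiblast, at 563 and 3854 CPM on average.

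Most genes of the ExE and trophectoderm lists were higher in ExE. Of 30 genes of the ExE and trophoblast stem cell list, 24 rose and 0 fell, and 26 and 1 adjusted over the list alone (camera adjusted p = 2.82e-57, adjusted p = 0.0099 with an estimated correlation). The FGF receptor Fgfr2 rose from 9.24 ± 2.89 to 405 ± 73.9 CPM and the transcription factor Tead4 from 1.61 ± 0.421 to 83.9 ± 27.3 CPM. Of 32 trophectoderm genes, 20 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.07e-28, adjusted p = 0.00488 with an estimated correlation). Of 17 ectoplacental cone and giant cell genes, 5 rose and 0 fell, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.000633, adjusted p = 0.0848 with an estimated correlation). Its camera test and mean log2 fold change of 1.25 were positive and its median was −0.24, also with the gene without counts in a group at its bound. The gap junction gene Gjb3 reached 455 ± 70.4 CPM, and 3 members of that list rose without ExE replicate 1 and Epiblast replicate 1 together. Of 23 primed epiblast genes, 0 rose and 13 fell, and 1 and 13 adjusted over the list alone (camera adjusted p = 1.05e-07, adjusted p = 0.0286 with an estimated correlation), among them Lin28b (log2 fold change −4.80) and Lef1 (−5.29).

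Genes of naive pluripotency split in ExE. Of 19 members, 6 rose and 6 fell, and 6 and 7 adjusted over the list alone. The nuclear receptor genes Esrrb (62.3 ± 19.6 against 0.311 ± 0.0501 CPM) and Nr0b1 (75.5 ± 13.9 against 1.66 ± 0.319 CPM) rose with Klf5 and Zfp42 (log2 fold changes 5.56 and 5.79). The camera test pointed up (adjusted p = 0.0344, adjusted p = 0.47 with an estimated correlation), as did the mean of 0.27, while the median log2 fold change was −0.55.

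Signalling genes went both ways. Of 36 WNT genes, 2 rose and 12 fell, and 3 and 18 adjusted over the list alone (camera adjusted p = 0.00891, adjusted p = 0.543 with an estimated correlation), the 2 being Wnt6 and Wnt7b. By limma on log2(TPM + 1), 4 WNT genes rose and 19 fell. Of 30 NODAL and BMP genes, 7 rose and 12 fell, and 9 and 12 adjusted over the list alone (camera adjusted p = 0.652). The ligand Bmp4 stood at 153 ± 39.2 against 3.05 ± 0.00571 CPM and Id3 at 8.62 ± 7.88 against 251 ± 5.36 CPM. Of 28 FGF genes, 8 rose and 9 fell, and 9 and 10 adjusted over the list alone (camera adjusted p = 0.499), a majority of falls that turned to 9 and 7 by limma on log2(TPM + 0.1). That test pointed up while the list's median log2 fold change was −0.40 and its mean −0.81, and the median was 0.01, with 8 rises and 7 falls, without ExE replicate 1 and Epiblast replicate 1 together.

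Stress and glycolysis genes were counted in the same contrast. Of 22 immediate-early and stress genes of the dissociation list, 12 rose and 0 fell, and 15 and 0 adjusted over the list alone (camera adjusted p = 4.03e-07, adjusted p = 0.372 with an estimated correlation). The immediate-early gene Fos stood at 582 ± 266 against 71.5 ± 16.9 CPM. Of 23 glycolysis genes, 12 rose and 1 fell, and 13 and 1 adjusted over the list alone (camera adjusted p = 0.000139, adjusted p = 0.537 with an estimated correlation), among them the hexokinase Hk1 (log2 fold change 3.52), and 6 rose and 1 fell with TMM factors from genes of at least 20 CPM.

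Markers of neighbouring tissues were measured in the same contrast. Of 30 primitive and visceral endoderm genes, 1 rose and 23 fell, and 1 and 24 adjusted over the list alone (camera adjusted p = 3.92e-14, adjusted p = 0.155 with an estimated correlation). The Epiblast libraries held 132 ± 49.6 CPM of the apolipoprotein Apoa1, made by visceral endoderm, and 30.8 ± 8.3 CPM of Afp. Without ExE replicate 1 and Epiblast replicate 1 together, 15 of the 30 endoderm genes and 5 of the primitive streak and mesoderm genes fell. Of 22 primitive streak and mesoderm genes, 3 rose and 8 fell, and 3 and 10 adjusted over the list alone (camera adjusted p = 0.00891, adjusted p = 0.543 with an estimated correlation). The organiser gene Gsc stood at 0.135 ± 0.093 against 14.8 ± 9.16 CPM. None of 19 decidua and blood genes passed the test, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.209), while limma on log2(TPM + 1) called 1 higher and 7 lower. Of 8 Y-linked genes and Xist, 0 rose and 1 fell, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.222), and with library totals 0 fell.

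Of 20264 genes tested by edgeR's quasi-likelihood test, 3814 differed between ExE and Epiblast, 2518 higher and 1296 lower in ExE. It was 5756 by limma on log2(TPM + 1), 3481 with a replicate block, 2408 without Epiblast replicate 1, 2107 without Epiblast replicate 2 and 1963 without ExE replicate 2. The split depended on scaling, since 66% of changed genes were higher by TMM, 50.6% by library totals, 45.2% by limma on log2(TPM + 1) and 46.6% with TMM factors from genes of at least 20 CPM, while the median log2 fold change of all genes was −0.33 by TMM and −0.57 by library totals.

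TE and ICM, the first lineages to separate, were compared at E3.5. ICM held the primitive endoderm factors Sox17 (58.5 ± 5.29 against 0.13 ± 0.00482 CPM in TE, log2 fold change −8.79, adjusted p = 0.000148) and Gata4 (46 ± 17.8 against 0.153 ± 0.00876 CPM, log2 fold change −8.21, adjusted p = 8.14e-05). It also held the ligand Bmp4 (65.8 ± 6.91 against 0.933 ± 0.792 CPM, log2 fold change −6.10, adjusted p = 0.000102). TE held more of the transcription factor Gata2 (325 ± 24.5 against 30.1 ± 7.41 CPM, log2 fold change 3.43, adjusted p = 0.000301), of the T-box factor Eomes (474 ± 148 against 94.3 ± 14.5 CPM, log2 fold change 2.33, adjusted p = 0.000862) and of the ephrin ligand Efna1 (58.5 ± 17 against 1.93 ± 1.47 CPM, log2 fold change 4.93, adjusted p = 0.000224). Cdx2 rose by a log2 fold change of 1.75 (adjusted p = 0.00408), a call lost without ICM replicate 1 (1.24, adjusted p = 0.062).

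Of 32 trophectoderm genes, 27 rose and 1 fell in TE, and 29 and 2 adjusted over the list alone (camera adjusted p = 1.8e-20, adjusted p = 0.00488 with an estimated correlation). The ICM libraries still held these transcripts, the fatty acid binding protein Fabp3 at 900 ± 51 CPM against 3505 ± 435 CPM in TE. Over 28 members with at least 20 CPM in TE, the median level in ICM was 27% of that in TE. Of 19 naive pluripotency genes, 1 rose and 11 fell in TE, and 1 and 11 adjusted over the list alone (camera adjusted p = 5.23e-08, adjusted p = 0.0597 with an estimated correlation). Of 30 primitive and visceral endoderm genes, 2 rose and 12 fell, and 3 and 14 adjusted over the list alone (camera adjusted p = 1.83e-06, adjusted p = 0.309 with an estimated correlation). Of 23 primed epiblast genes, 1 rose and 9 fell, and 1 and 11 adjusted over the list alone (camera adjusted p = 3.93e-08, adjusted p = 0.0438 with an estimated correlation). Of 25 cholesterol synthesis genes, 10 rose and 0 fell, and 16 and 0 adjusted over the list alone (camera adjusted p = 4.69e-05, adjusted p = 0.463 with an estimated correlation), among them Insig1 (log2 fold change 1.62). With library totals, by limma on log2(TPM + 1) or with TMM factors from genes of at least 20 CPM, 3 of them rose and 0 fell. Of 28 Polycomb genes, 8 rose and 1 fell, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0452, adjusted p = 0.695 with an estimated correlation), a direction that turned to 3 and 6 with library totals. The Polycomb cofactor Mtf2 stood at 1438 ± 194 against 512 ± 53.6 CPM.

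Between TE and ICM, 3563 genes changed, 2567 higher and 996 lower in TE. It was 3145 with a replicate block, 1644 without ICM replicate 1, 2020 without ICM replicate 2, 1845 without TE replicate 1 and 1858 without TE replicate 2. The split turned with scaling, from 72% higher in TE by TMM to 35.1% by library totals, 41% by limma on log2(TPM + 1) and 42.6% with TMM factors from genes of at least 20 CPM. The median log2 fold change of all genes was 0 by TMM and −0.47 by library totals.

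The lineage difference at E6.5 was set against that at E3.5 to ask whether trophoblast and embryonic cells part in the same way at both stages. Hand1, a basic helix-loop-helix factor of trophoblast, stood at 137 ± 26 CPM in ExE against 0.381 ± 0.3 in Epiblast, and at 0.47 ± 0.138 CPM in TE against 7.94 ± 4.45 in ICM (difference of log2 fold changes 12.57, adjusted p = 8.06e-06). Esrrb was likewise higher in ExE than in Epiblast and lower in TE than in ICM (difference 11.97, adjusted p = 8.06e-06). Elf5 differed by 9.32 (adjusted p = 0.000274), Dnmt3a by −4.68 (adjusted p = 8.06e-06) and Dnmt3b by −2.47 (adjusted p = 5.69e-05). Of 30 genes of the ExE and trophoblast stem cell list, 21 differed towards ExE and 1 the other way, and 22 and 1 adjusted over the list alone (camera adjusted p = 8.88e-55, adjusted p = 0.00906 with an estimated correlation). Of 19 naive pluripotency genes, 9 differed towards ExE and 2 the other way, and 10 and 2 adjusted over the list alone (camera adjusted p = 6.66e-12, adjusted p = 0.0286 with an estimated correlation). The median log2 fold change of this list was −0.55 between ExE and Epiblast and −2.3 between TE and ICM. A difference towards ExE is therefore not in itself a rise in ExE.

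The difference of the changes passed the test for 2013 genes, 941 towards ExE and 1072 the other way, 46.7% towards ExE against 63.5% with library totals and 54.9% with TMM factors from genes of at least 20 CPM. It passed for 3881 genes by limma on log2(TPM + 1), for 3044 on log2(TPM + 0.1) and for 1758 with a replicate block. Across the 20264 genes, which are not independent replicates, the log2 fold changes of both stages had Pearson r = 0.282 and Spearman rho = 0.406. That r was 0.098 without Epiblast replicate 2, 0.158 without ExE replicate 2 and 0.168 without ICM replicate 2. Of 1547 genes called at both stages, 1240 (80.2%) had the same direction. By TMM, 988 were higher in both trophoblast tissues where independent lists would share 319, and 252 were lower in both against 63.7. In opposite directions, 119 were higher in ExE and lower in TE against 123.8, and 188 the reverse against 164.2. With library totals, 947 of 1354 had the same direction, 447 higher in both against 109.1 and 500 lower in both against 197.6. Background on the receptor genes, in CPM per kilobase, was 0.636 and 0.422 in ICM against 0.0551 and 0.172 in TE. It was 0.472 and 0.894 in Epiblast against 0.504 and 0.0611 in ExE. Receptor genes with a count numbered 697 and 640 in ICM, 238 and 529 in TE, 927 and 1189 in Epiblast, and 1107 and 426 in ExE. In ICM replicate 1, 31697 counts lay on those 697 genes, while Epiblast replicate 1 held 23072 on 927. Expression of single receptor genes was not separated from background. Whether a shared difference in background adds to the correlation and the shared direction was not tested.

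Epiblast and ICM were compared to follow the embryonic lineage from E3.5 to E6.5. Per the labels, zygotes were grown in KSOM, blastocysts were parted by laser and E6.5 conceptuses were bisected. Differences in culture and collection therefore cannot be told apart from stage. Epiblast rose in the growth factor Fgf15 (76.3 ± 1.46 CPM against 0 counts in ICM, at least 2600-fold) and in the transcription factors Pou3f1 (170 ± 48 against 0.635 ± 0.26 CPM, log2 fold change 8.07) and Otx2 (214 ± 37 against 6.23 ± 0.0943 CPM, log2 fold change 5.10, adjusted p = 0.000425). Khdc3, an oocyte and early embryo gene, fell from 1966 ± 164 to 0.314 ± 0.115 CPM (log2 fold change −12.62, adjusted p = 2.51e-09). Dnmt3b rose by 4.13 (adjusted p = 6.77e-08) and Dnmt3a by 3.20 (adjusted p = 9.08e-07), and Dnmt3l fell by 2.59 (adjusted p = 2.62e-06). Pou5f1 was at 483 ± 12.6 and 520 ± 29.1 CPM and did not pass the test (adjusted p = 0.951).

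Of 19 naive pluripotency genes, 0 rose and 15 fell in Epiblast, and 0 and 15 adjusted over the list alone (camera adjusted p = 6.53e-19, adjusted p = 0.0215 with an estimated correlation). The Krüppel-like factor Klf5 fell from 391 ± 20.5 to 2.46 ± 0.328 CPM. Of 23 primed epiblast genes, 15 rose and 1 fell, and 17 and 1 adjusted over the list alone (camera adjusted p = 2.18e-09, adjusted p = 0.0286 with an estimated correlation). Of 32 trophectoderm genes, 1 rose and 25 fell, and 1 and 25 adjusted over the list alone (camera adjusted p = 6.26e-36, adjusted p = 0.00483 with an estimated correlation). In the ICM libraries the median level of 28 of these genes was 27% of that in TE. TE carried over into those libraries was not separated from a change in the embryonic lineage. Of 23 glycolysis genes, 18 rose and 1 fell, and 20 and 1 adjusted over the list alone (camera adjusted p = 1.85e-18, adjusted p = 0.126 with an estimated correlation). The lactate dehydrogenase Ldhb stood at 179 ± 10.2 against 0.514 ± 0.177 CPM. Of 73 oxidative phosphorylation genes, 0 rose and 38 fell, and 0 and 45 adjusted over the list alone (camera adjusted p = 3.89e-06, adjusted p = 0.785 with an estimated correlation). Of 36 cell cycle genes, 18 rose and 4 fell, and 19 and 4 adjusted over the list alone (camera adjusted p = 0.00749, adjusted p = 0.622 with an estimated correlation). The cyclin gene Ccne1 rose by a log2 fold change of 2.19. Markers of another tissue were measured beside these lists. Of 30 primitive and visceral endoderm genes, 13 rose and 8 fell, and 13 and 9 adjusted over the list alone (camera adjusted p = 0.3), with Apoa1 at 132 ± 49.6 CPM in Epiblast and 4.73 ± 3.82 in ICM. In total 6031 genes changed, 2960 higher and 3071 lower in Epiblast, 49.1% higher against 59.9% by limma on log2(TPM + 1), 52.2% with library totals and 33.6% without ExE replicate 1 and Epiblast replicate 1 together.

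ExE and TE were compared to follow the trophoblast over the same interval, with the same limit that culture and collection cannot be told apart from stage. ExE held carbonic anhydrase Car2 (371 ± 87.6 CPM against 0 counts in TE, at least 10500-fold) and the retinoic acid hydroxylase Cyp26a1 (195 ± 45.5 CPM against 0 counts, at least 5540-fold). The lactate dehydrogenase Ldha rose from 5.19 ± 1.28 to 5096 ± 1130 CPM (log2 fold change 9.93) and the glucose transporter Slc2a1 from 74.8 ± 0.383 to 1499 ± 344 CPM (log2 fold change 4.33). The imprinted RNA H19 rose from 0.946 ± 0.505 to 658 ± 249 CPM (log2 fold change 9.47), and the homeobox gene Rhox5 from 13.5 ± 2.4 to 1597 ± 489 CPM (log2 fold change 6.89). Khdc3 fell from 1647 ± 172 to 0.154 ± 0.0758 CPM (log2 fold change −13.39). Dnmt1 rose by 2.15 (adjusted p = 5.58e-06) and Dnmt3b by 1.65 (adjusted p = 1.39e-05), and Dnmt3a fell by 1.48 (adjusted p = 0.000193).

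Pluripotency lists were counted between ExE and TE. Of 23 primed epiblast genes, 15 rose and 1 fell, and 15 and 2 adjusted over the list alone (camera adjusted p = 8.6e-07, adjusted p = 0.0438 with an estimated correlation). Without ExE replicate 1, the library with more Pou5f1, and Epiblast replicate 1 together, 9 of them rose and 2 fell. Of 19 naive pluripotency genes, 4 rose and 12 fell, and 4 and 15 adjusted over the list alone (camera adjusted p = 0.000201, adjusted p = 0.193 with an estimated correlation). Of 39 imprinted genes, 19 rose and 4 fell in ExE, and 22 and 4 adjusted over the list alone (camera adjusted p = 3.07e-09, adjusted p = 0.0286 with an estimated correlation). Of 23 glycolysis genes, 19 rose and 3 fell, and 19 and 3 adjusted over the list alone (camera adjusted p = 5.57e-24, adjusted p = 0.102 with an estimated correlation). Of 73 oxidative phosphorylation genes, 1 rose and 55 fell, and 1 and 58 adjusted over the list alone (camera adjusted p = 7.85e-09, adjusted p = 0.683 with an estimated correlation). Without ExE replicate 1 and Epiblast replicate 1 together, 2 rose and 36 fell. The respiratory chain gene Cox5a stood at 208 ± 38.6 against 685 ± 16.1 CPM. Of 32 trophectoderm genes, 5 rose and 22 fell, and 5 and 23 adjusted over the list alone (camera adjusted p = 1.95e-18, adjusted p = 0.00596 with an estimated correlation). The endocytic adaptor Dab2 fell from 1379 ± 56.4 to 4.84 ± 0.253 CPM.

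Other lists were counted between ExE and TE. Of 136 developmental transcription factors, 20 rose and 23 fell, and 20 and 23 adjusted over the list alone (camera adjusted p = 0.913), a majority of falls that turned to 19 and 18 by limma on log2(TPM + 1). Its camera test pointed down while its median log2 fold change was 0.43, or 0.30 with genes without counts in a group at their bound, and its mean was 0.19. That median was −0.56, with 13 rises and 18 falls, without ExE replicate 1 and Epiblast replicate 1 together. Of 29 clustered protocadherins, 6 rose and 0 fell, and 2 and 0 adjusted over the list alone (camera adjusted p = 0.174). The protocadherin Pcdhgc3 stood at 9.37 ± 0.542 CPM against 0 counts in TE. Of these genes, 1 rose without ExE replicate 1 and Epiblast replicate 1 together, and 3 by limma on log2(TPM + 1). Counts on the receptor genes, in CPM per kilobase, were 0.504 and 0.0611 in ExE and 0.0551 and 0.172 in TE. Of 85 ribosomal protein genes, 0 rose and 5 fell, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.981), a direction that turned to 56 and 3 by limma on log2(TPM + 1). Its test and median log2 fold change of 0.05 pointed up and its mean of −0.06 down. In total 6232 genes changed, 2796 higher and 3436 lower in ExE, 44.9% higher against 58.9% with library totals, 61.7% by limma on log2(TPM + 1) and 53.6% with TMM factors from genes of at least 20 CPM.

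ICM and TE were each compared with the 8-cell stage to describe the step to the blastocyst. The 8-cell embryos had been held with aphidicolin, so in both contrasts that treatment cannot be told apart from stage. The water channel Aqp8 reached 76.3 ± 36.9 CPM in ICM against 0 counts at the 8-cell stage, at least 2220-fold, and the secreted glycoprotein Spp1 rose from 3.55 ± 3.49 to 1410 ± 562 CPM (log2 fold change 8.64, adjusted p = 1.72e-05). In TE, Gata2 rose from 0.162 ± 0.165 to 325 ± 24.5 CPM (log2 fold change 10.96, adjusted p = 2.14e-07) and the peptide transporter Slc15a2 from 0.441 ± 0.362 to 941 ± 71 CPM (log2 fold change 11.04). The homeobox gene Obox6 fell from 904 ± 20.9 CPM to 7.69 ± 0.92 in ICM and 2.15 ± 1.09 in TE (log2 fold changes −6.88 and −8.69). Gata4, at 133 ± 24.5 CPM in 8-cell embryos, was lower in TE (log2 fold change −9.73, adjusted p = 1.02e-06).

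Of 22 p53 targets, 1 rose and 16 fell in ICM, and 1 and 17 adjusted over the list alone (camera adjusted p = 2.76e-07, adjusted p = 0.355 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1a stood at 219 ± 66.5 CPM in 8-cell embryos, which had been held with aphidicolin, and at 8.77 ± 5.54 in ICM. In TE, 2 rose and 17 fell, and 2 and 17 adjusted over the list alone (camera adjusted p = 9.23e-06, adjusted p = 0.416 with an estimated correlation). Of 32 germline genes, 2 rose and 18 fell in ICM, and 2 and 18 adjusted over the list alone (camera adjusted p = 0.00819, adjusted p = 0.364 with an estimated correlation). The germline factor Dmrtb1 fell from 99.9 ± 25 to 0.0307 ± 0.0434 CPM. Of 32 oocyte and two-cell genes, 2 rose and 12 fell in TE, and 3 and 14 adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.695 with an estimated correlation), the 2 being Ooep and Khdc3, and 19 fell by limma on log2(TPM + 1). Of 73 oxidative phosphorylation genes, 64 rose and 0 fell in TE, and 66 and 0 adjusted over the list alone (camera adjusted p = 4.36e-18, adjusted p = 0.543 with an estimated correlation). Of 32 trophectoderm genes, 26 rose and 2 fell in TE, and 26 and 2 adjusted over the list alone (camera adjusted p = 3.21e-32, adjusted p = 0.00483 with an estimated correlation). Of the same genes, 24 rose and 5 fell in ICM, and 25 and 5 adjusted over the list alone (camera adjusted p = 8.88e-18, adjusted p = 0.00569 with an estimated correlation). In ICM, the median level of 28 of these genes was 27% of that in TE, and carry-over of TE was not separated from expression in ICM cells. Against the 8-cell stage, 6710 genes changed in ICM, 2827 higher and 3883 lower, and 7438 in TE, 3771 higher and 3667 lower. The share of higher genes in ICM was 42.1%, against 60.8% with library totals, 56.5% with no filter on low counts and 53.6% with TMM factors from genes of at least 20 CPM. The share in TE was 50.7% against 45.3% by limma on log2(TPM + 1) and 46.3% with those TMM factors.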

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

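The tests on sequencing depth, on visceral endoderm, on the low-level background of ExE replicate 1 and on carry-over of trophectoderm were chosen only after the result was seen.

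The change between ExE and Epiblast differed from that between TE and ICM, by a test of the difference itself, for 21 named genes. Of these, 12 were named for the largest differences among genes that passed this test, so their passing was fixed in advance. The other 9 are reference genes, chosen before the data were examined. Apoa1, Spink1 and Ttr are members of the primitive and visceral endoderm list. The adjusted p of the difference was 8.06e-06 for each of Nr0b1, Hand1, Nup62cl, Esrrb and Dnmt3a, 3.99e-05 for Gjb4, 4.06e-05 for Apoa1, 5.25e-05 for Cdx2 and 5.69e-05 for Dnmt3b. It was 0.000182 for Dnmt3l, 0.000274 for Elf5, 0.000339 for Slain1, 0.00226 for Rab17, 0.00469 for Scarf2, 0.0101 for Pou5f1, 0.0119 for Spink1 and 0.0122 for Dnmt1. It was 0.0173 for Nanog, 0.0195 for Crmp1, 0.0222 for Ttr and 0.0318 for Otx2. Hand1, Nup62cl and Esrrb were lower in TE than in ICM and higher in ExE than in Epiblast, with differences of 12.57, 11.99 and 11.97 on the log2 scale. Nr0b1 and Scarf2 had 0 counts in TE and stood at 75.5 ± 13.9 and 31.7 ± 9.42 CPM in ExE, and Crmp1 had 0 counts in ICM and stood at 66.2 ± 7.06 CPM in Epiblast.

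Some of these calls were lost without a single library. Crmp1 and Spink1 had an adjusted p of 1 without TE replicate 2, when the remaining TE library held 0 counts of either gene, and Scarf2, with 0 counts in TE, had one of 0.0993 without ICM replicate 1. Ttr, with 3 counts in ICM, lost its call without ICM replicate 2 (adjusted p = 0.0595), TE replicate 1 (0.471), Epiblast replicate 1 (0.0657) or ExE replicate 2 (0.052). Otx2, with a difference of −3.88 on the log2 scale, lost it without ICM replicate 1 (−3.69, adjusted p = 0.0746), ICM replicate 2 (−3.68, 0.0773), TE replicate 1 (−3.32, 0.116) or Epiblast replicate 1 (−3.48, 0.0757). Nanog, with one of −2.40, lost it without ICM replicate 2 (−1.98, adjusted p = 0.0768), TE replicate 1 (−2.19, 0.052) or Epiblast replicate 1 (−1.95, 0.0659).

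Transcripts matched to no gene held 2.37% of the counts of Epiblast replicate 1, the highest share of the 10 libraries, of which 1.67% lay on a ribosomal RNA entry.

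The number of genes with at least 10 counts ran from 14633 to 18915 over the 10 libraries. Sequencing depth was argued against, since that number fell as library totals rose (Spearman rho −0.782, permutation p = 0.0104; Pearson r −0.73, and −0.373 without the 2 libraries farthest from the median). Background may contribute, since the number rose with counts per kilobase on 1459 receptor genes (rho 0.891, permutation p = 0.00125). Pearson r was 0.888 (permutation p = 0.00034), and 0.885 without the 2 farthest. Genomic DNA and unspliced RNA cannot be told apart by these counts. The number includes the receptor genes, of which 238 (TE replicate 1) to 1189 (Epiblast replicate 2) held a count, so part of this relation is built in. The permutations treated the 10 libraries as exchangeable, though they form 5 groups of 2. The number of genes and the receptor counts ordered the 2 libraries alike in 4 of 5 groups. A difference between tissues in the number of expressed genes was not tested and stays open.

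Pou5f1 stood at 24.1 CPM in ExE replicate 1 and 2.38 in ExE replicate 2, and transcripts of Epiblast were examined on 37 genes chosen for standing at least 50 times higher in Epiblast than in ExE replicate 2, a choice that favours higher values in ExE replicate 1. Epiblast cells carried over at the bisection cannot be told apart from other sources, since the implied share had a median of 4.4% and its upper quartile was 2.24 times the lower, between the bounds of 2 and 4 set for the test. Visceral endoderm carried along in the ratio of the Epiblast libraries was left undecided by 13 genes, of which 53.8% lay below the bound. Their median implied share of 1.41%, against 4.4% for the epiblast genes, was itself below that bound. Exclusion also needed a larger part of the 13 below it. Of these genes, 69.2% were higher in ExE replicate 1. The low-level background of ExE replicate 1 was also undecided, since the median excess was 3.66 times the receptor-gene level and 67.6% of the genes exceeded it by more than 2 times, Pou5f1 by 41.2. A difference between the embryos of the ExE libraries was not tested.

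ICM held trophectoderm transcripts, with a median of 27% of their TE level over 28 list members and quartiles of 20% and 34.7%. Carry-over of average TE as the whole cause stayed within the bounds set, with an upper quartile 1.73 times the lower, so the test did not exclude it. Of 196 genes with at least 100 CPM in TE and 10-fold over 8-cell embryos, 3 lay below 9% of their TE level in both ICM libraries. The test, chosen after the result was seen, needed 20 such genes to exclude carry-over. Those 3 were BC051665 at 0.438%, Gm4926 at 3.1% and S1pr5 at 7.57% of their TE level. Though too few for that bound, these 3 argue against carry-over of average TE at one ratio as the sole source of the 27% median. The lowest list member was Gata2 at 9.27%. Carry-over of polar TE cannot be told apart from that of average TE, because 0 libraries of polar TE were measured. Expression of these genes in ICM cells themselves was not tested and stays open.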

How the results depend on the processing

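Leaving out ExE replicate 1 with Epiblast replicate 1, keeping genes of at least 5 CPM and taking TMM factors from genes of at least 20 CPM were chosen after seeing the data. Of 708 called results of named genes, 1 was lost with DESeq2 size factors, 5 with DESeq2, 27 with library totals, 36 with limma on log2(TPM + 1), 9 with a replicate block over all groups and 12 to 48 without 1 library. Apart from the 10 reference genes, named genes were picked for large folds or small adjusted p in the main fit. That choice favours few losses, so these counts do not speak for all changed genes. DESeq2 made 34 calls where nothing changed in the simulation, so its few losses are weak support. A stricter hypothesis, a log2 fold of 1, lost 125 of the 708. Of 78 called lists, 18 held with an estimated correlation and 77 with a replicate block. fry, which compares a list with no change rather than with other genes, passed 69 of them. In a simulation with 2 libraries per group, 12% of genes changed by a log2 fold of 1 were recovered, and depth was not varied in it. It changed 100 genes at each fold among 20264, in ExE alone, while 3814 were called in the data. The Benjamini-Hochberg cut is stricter with fewer changed genes, so that share does not measure recovery in the data.

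Against a log2 fold of 1, the counts of changed genes were 1187 between ExE and Epiblast, 713 between TE and ICM, 2855 between Epiblast and ICM, 2881 between ExE and TE, 3128 between ICM and 8-cell, 3862 between TE and 8-cell and 864 for the difference, a stricter hypothesis by construction. limma on log2(TPM + 1) gave 5756 between ExE and Epiblast and 3881 for the difference, which was 3044 on log2(TPM + 0.1) and 3970 with a TPM of at least 1; the cause was not tested. Without 1 library, counts ran from 1963 (ExE replicate 2) to 4316 (ExE replicate 1) between ExE and Epiblast, and from 1644 (ICM replicate 1) to 3448 (8-cell replicate 2) between TE and ICM. The correlation of both lineage changes ran from 0.098 (Epiblast replicate 2) to 0.397 (ExE replicate 1), was 0.417 without the first ExE and Epiblast libraries together, and 0.258 with a replicate block.

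Signs turned for reference genes that had not passed the test. Eomes between Epiblast and ICM was −0.141 with no filter, −0.057 with the groups of the contrast alone and −0.476 without the first ExE and Epiblast libraries, and ran from −0.476 (Epiblast replicate 1) to 0.289 (Epiblast replicate 2) without 1 library. Pou5f1 there was 0.055 in all 3 limma settings. Dnmt3l between ExE and TE was 0.203 with library totals, 0.105 with the groups alone, 0.278 and 0.28 by limma, 0.1 with TMM factors from genes of at least 20 CPM and 0.004 without the first ExE and Epiblast libraries, and ran from −0.239 (TE replicate 1) to 0.1 (TE replicate 2). Otx2 between ExE and TE was −1.331 without those libraries and ran from −1.335 (ExE replicate 1) to 2.111 (ExE replicate 2, adjusted p = 0.00162). Eomes ran from −0.218 (ExE replicate 2) to 0.482 (TE replicate 2) between ExE and TE and from −0.22 (TE replicate 1) to 0.623 (TE replicate 2) in the difference. Dnmt3a between TE and 8-cell ran from −0.282 (8-cell replicate 2) to 0.056 (TE replicate 2). The causes were not tested.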

Other observations

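The values of transcript forms in this part were chosen only after they were seen, and no test was run on them.

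The most abundant transcript form of Dnmt3a was not the same at each stage. The form of 9735 bases held 99.8 ± 0.344% of the gene's TPM in 8-cell embryos, 95.9 ± 3.3% in ICM and 97.8 ± 0.912% in TE (SD, n = 2). The form of 8913 bases held 84 ± 3.03% in Epiblast. The ExE libraries differed, with 4 TPM of the form of 8913 bases, 1.48 TPM of that of 9735 bases and 1.95 TPM of that of 9689 bases in ExE replicate 1, in which Pou5f1 was also higher. In ExE replicate 2 these forms stood at 1.39, 1.9 and 0.617 TPM. For Dnmt3l, the form of 1295 bases held 54.8 ± 2.76% in 8-cell embryos and 2.7 ± 0.842% in ICM, and was listed at 0 in Epiblast and ExE. Of the Dnmt3b forms, those of 4226, 4166, 4037 and 3977 bases were listed at 0 TPM in both 8-cell libraries, and the form of 4226 bases stood at 260 ± 11.2 TPM in Epiblast.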
